A study of Mus musculus with 6 samples.

How the data were processed

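Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wild-type CD1 mouse embryos at embryonic day 13.5. The tissues were molar tooth germ and limb. Per the labels' protocols, tissue was fixed in 1% formaldehyde for 15 min, sonicated, precipitated with antibodies to pSmad1/5 or to Smad4, and sequenced on a HiSeq 4000. pSmad1/5 is the phosphorylated, active form of the receptor-regulated Smads of bone morphogenetic protein (BMP) signalling, and Smad4 is the partner shared with the TGF-beta branch. The series holds 6 samples. Of these, 4 have a peak list (1 library for each tissue and antibody) and 2 are input samples, whose signal was not used here.

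The authors called peaks with BCP in its transcription factor mode, per the labels, and deposited 1 list per library. Bowtie2, SAMtools, bedtools, deepTools and bcl2fastq are named in the submitters' processing notes without versions or roles, and the genome build there is mm10. Whether the inputs served as controls of the peak calls, and how duplicates and problem regions were handled, is not given in the sources used here. Each list gives, per the labels, the position, length and summit of a peak, an enrichment score and a p-value. The deposited enrichment score is the authors' own value per peak and served only to rank or filter peaks. The deposited p-value lay under 0.001 for every peak and was not used for any test. The lists hold no read counts, so the sequencing depth of each library is unknown.

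Gene positions came from RefSeq on GRCm38.p6, whose primary chromosomes carry the coordinates of mm10. That table gives the start and end of each gene without its strand. The design had set distances from transcription start sites, and distances from either annotated end of a gene were used in their place. Peaks were classed as near a gene end (summit within 1 kb), otherwise inside a gene, or outside genes. Exons, introns and untranslated regions were not separated. No genome sequence was used here, so the planned count of sequence motifs was not run. There were 21887 protein-coding genes.

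Peaks of different lists were called shared when they overlapped by at least 1 bp. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error over peaks only and say nothing about variation between animals. Chance overlap was taken from 1000 circular shifts of the partner list within chromosomes. A second chance level, from 1000 shifts of 5 to 50 kb, keeps the local density of peaks. A gene counted as having a peak when a summit lay within 50 kb of either end. The counts of 18 gene lists and 21 gene families were placed among 10000 random lists of as many protein-coding genes, matched in 5 bins of local gene density. These percentiles describe these libraries. With 1 library per group no p-value was computed, and no difference between tissues or antibodies has a replicate check.

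The gene lists, the overlap rule, most alternative settings and the rule for named genes were fixed before the data were examined. By that rule the text names 22 fixed genes, the genes nearest to the 5 highest-scoring peaks of each sharing class and of each tissue-restricted set, and up to 4 members per list with a peak in a single tissue. A few genes that the rule selects are not reported here. Names outside the rule were chosen after their values were seen and are introduced as such. The added alternatives were a minimum score of 4 in all lists, equal numbers of top-scoring peaks on each chromosome, local shifts, random lists matched on gene length or drawn from the same chromosomes, gene lists at shared sites, and the limb patterning list without Hox genes and against random lists in the filtered peak lists.

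Overlap and list counting were tested on simulated data. Of 1169 shared peaks placed at random into limb lists of 23389 peaks, 1169 were recovered as excess over shifts, and 1768 of 1773 in molar lists of 35476 peaks. Random lists had a median percentile of 51.8 for limb Smad4. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.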

Results

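The data comprised 4 lists of genomic sites, for pSmad1/5 and for Smad4 in molar tooth germ and in limb of E13.5 embryos, with 1 library each. The limb lists held 23389 pSmad1/5 peaks and 29756 Smad4 peaks. The molar lists held 35476 pSmad1/5 peaks and 34561 Smad4 peaks. Peaks were narrow, with median widths of 56, 58, 63 and 55 bp in that order. Read depth is unknown, so list length cannot be read as the amount of binding.

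Peak density was uneven between chromosomes in the molar lists and followed the lowest score listed on each chromosome. Rounded down, that score was 3 on all 19 autosomes of both limb lists. In the molar pSmad1/5 list it was 2 on 7 autosomes, with 18.4 to 25.2 peaks per Mb, and 3 on the other 12, with 6.89 to 11.4. In the molar Smad4 list it was 4 on chromosomes 2, 5, 8, 9, 11 and 19, with 3.16 to 4.55 peaks per Mb, and 3 on the other 13, with 12.2 to 19.9. The molar to limb ratio of peak numbers ran from 0.668 to 6.43 across autosomes for pSmad1/5 and from 0.207 to 3.08 for Smad4. With a score of at least 4 this ratio ran from 0.498 to 1.51 and from 0.381 to 2.19.

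**Figure D1:**
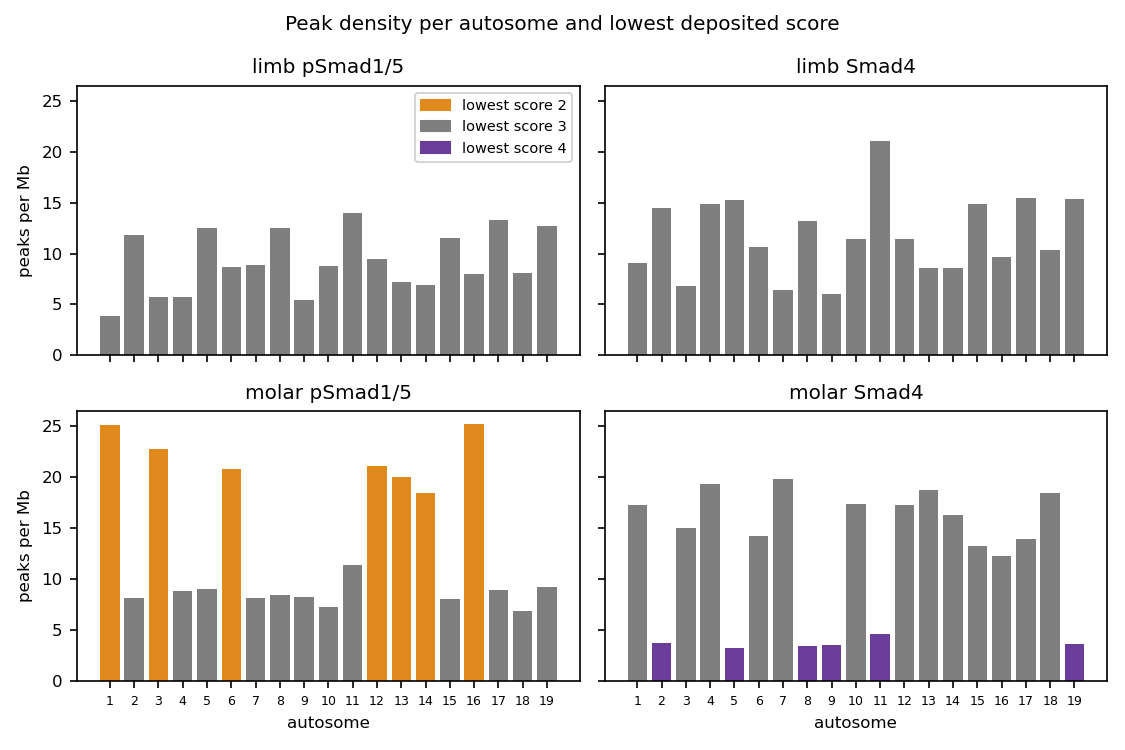
Peaks per Mb (vertical axis) on each autosome (horizontal axis) in the 4 libraries, coloured by the lowest score listed on that chromosome. The 6 purple chromosomes of the molar Smad4 list, with a lowest score of 4, hold 3.16 to 4.55 peaks per Mb and its other 13 hold 12.2 to 19.9.

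Sites near gene ends made up 14.8% of limb pSmad1/5 peaks (95% interval 14.4 to 15.3%), 17.99% of limb Smad4 peaks (17.6 to 18.4%) and 14.4% of molar pSmad1/5 peaks (14.0 to 14.8%). In the molar Smad4 list the share was 4.83% (4.60 to 5.06%). Shifting peaks by 5 to 50 kb gave 5.95%, 6.19%, 4.62% and 3.63% in the order limb pSmad1/5, limb Smad4, molar pSmad1/5 and molar Smad4. The observed share was therefore 2.49, 2.90 and 3.11 times the shifted share in the first 3 lists and 1.33 times in the molar Smad4 list. Other peaks inside genes made up 50.7%, 51.02%, 44.4% and 47.2% in that order, and peaks outside genes 34.5%, 30.99%, 41.2% and 47.96%.

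**Figure D2:**
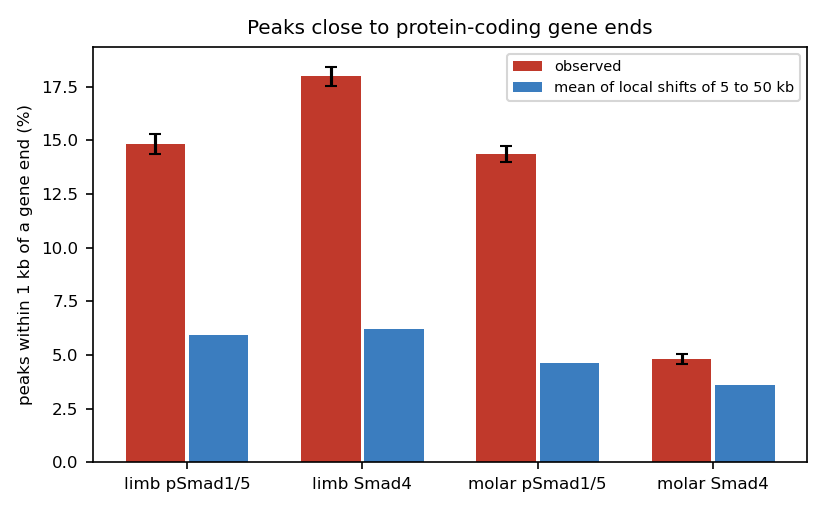
Percent of peaks with a summit within 1 kb of a protein-coding gene end (vertical axis) in each library. Red bars are observed shares with exact 95% binomial intervals and blue bars the mean after local shifts; the molar Smad4 share of 4.83% lies closest to its shifted value of 3.63%.

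The first comparison asks how much of the pSmad1/5 occupancy coincides with Smad4 in each tissue. In limb, 1134 of 23389 pSmad1/5 peaks overlapped a Smad4 peak, a share of 4.85% (4.58 to 5.13%). In molar, 209 of 35476 did, a share of 0.589% (0.512 to 0.674%). Seen from Smad4, 3.83% of limb peaks (3.62 to 4.06%) and 0.608% of molar peaks (0.528 to 0.695%) overlapped pSmad1/5. Examples of limb sites with a peak for both antibodies, chosen after their values were seen, lay at Bmp4 (summit at chromosome 14, 46390582, 87 bp from a gene end), the BMP effector Smad1 (chromosome 8, 79399105, 323 bp) and the hedgehog receptor Ptch1 (chromosome 13, 63572693, 767 bp). As groups, BMP-Smad targets (5 of 30, percentile 92.02) and BMP pathway genes (6 of 31, percentile 96.1) had shared limb sites within the range of random lists.

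Chance gave fewer shared sites in both tissues. Circular shifts gave a mean of 39.3 and at most 67 shared limb pSmad1/5 peaks, and a mean of 67.8 and at most 95 in molar. Local shifts gave means of 117.2 and 100.1. The limb overlap was 9.67 times the local chance level (counting interval 9.12 to 10.3) and the molar overlap 2.09 times (1.81 to 2.39). With a score of at least 4 on autosomes, limb kept 191 shared peaks and molar 10, at 22.6 times (19.5 to 26.0) and 3.88 times (1.86 to 7.13) local chance. Shared limb pSmad1/5 peaks scored somewhat higher than unshared ones, with medians of 3.69 and 3.43, whereas shared molar peaks had a median of 2.60 against 3.0003. The molar order was not stable: it turned to 4.97 against 4.36 with a score of at least 4, where 10 shared peaks remain, and to 3.57 against 3.48 with equal numbers of peaks per chromosome.

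**Figure D3:**
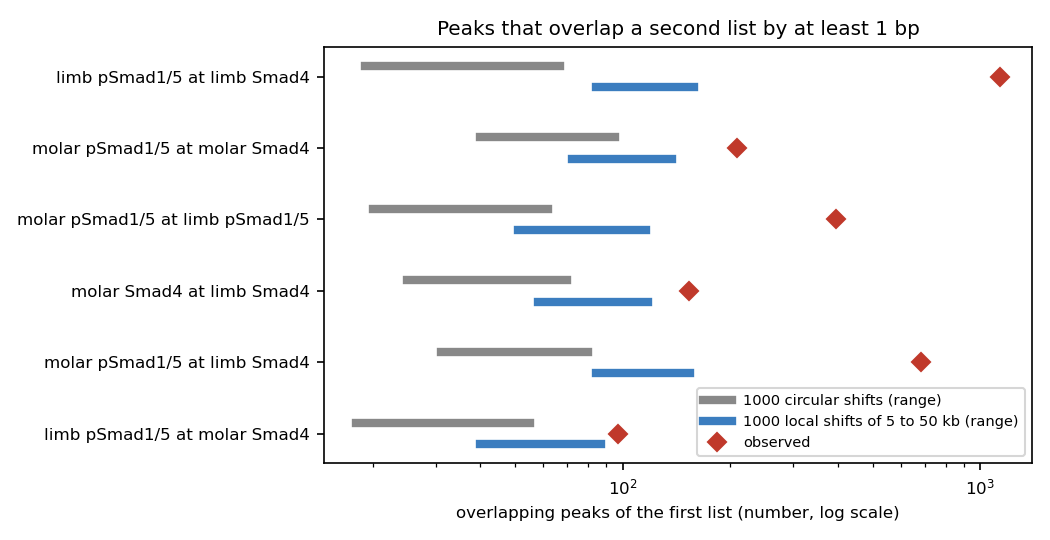
Number of peaks of the first list that overlap the second by at least 1 bp (horizontal log axis) for 6 pairs of libraries. Diamonds are observed numbers and bars the range of 1000 circular (grey) or local (blue) shifts; limb pSmad1/5 at limb Smad4 stands furthest out, with 1134 peaks.

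Gene ends were over-represented among limb sites with a peak for both antibodies. There, 39.2% of shared sites lay near a gene end (36.3 to 42.1%), against 13.6% of pSmad1/5 sites without Smad4 (13.1 to 14.0%) and 17.1% of Smad4 sites without pSmad1/5 (16.7 to 17.6%). In molar the shares were 16.7% (11.95 to 22.5%), 14.4% (14.0 to 14.7%) and 4.75% (4.53 to 4.98%).

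The genes of dental mesenchyme, a list of 40 regulators and signals of the tooth-forming connective tissue, were well represented at the shared limb sites. There, 11 of 40 had a shared site within 50 kb, against a median of 3 for random lists (percentile 99.985). Of the 40, 10 also stand in the limb patterning list, and of the latter list 2 of 45 had a shared limb site (percentile 19.5). Examples chosen after their values were seen are the hedgehog effector Gli2 (864 bp from a gene end) and the forkhead factor Foxf1 (776 bp). The Wnt family had 7 of 19 members at such sites (percentile 99.5), with Wnt7b at 71 bp, and the Fox family 10 of 44 (percentile 99.1). Neighbouring members share sites there (Wnt3a with Wnt9a, Wnt1 with Wnt10b, Foxc2 with Foxl1), so these counts exceed the number of distinct sites. In molar, shared sites lay within 50 kb of 0 of 40 dental mesenchyme genes and 0 of 45 limb patterning genes, where random lists also had a median of 0.

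The strongest shared limb sites lay inside Smo, the hedgehog signal transducer (chromosome 6, 29748835 to 29748889, score 12.8), 164314 bp from Tcte2 (chromosome 17, 13552090 to 13552136, score 12.2) and 2782 bp from Cbx7 (chromosome 15, 79973887 to 79973944, score 8.67). The next lay 23440 bp from Osr2, a regulator of tooth patterning (chromosome 15, 35326726 to 35326780, score 8.52), and inside Copg2, 56506 bp from Mest (chromosome 6, 30804852 to 30805021, score 8.42). In molar the strongest shared sites lay inside Emp2 (chromosome 16, 10284522 to 10284548, score 13.8), 2604 bp from Cwc22 (chromosome 2, 77878513 to 77878649, score 5.70), inside Fzr1 (chromosome 10, 81367529 to 81367591, score 5.41) and inside Ppp1r9b (chromosome 11, 94991737 to 94991811, score 5.13). The strongest limb peaks without the partner lay inside Cdk8 for pSmad1/5 (chromosome 5, 146261340 to 146261384, score 28.8), followed by Cwc22 (score 10.4), Tcp10c, Pde6h at 39236 bp (score 8.44) and Dennd1a at 239 bp from a gene end (score 8.02). For Smad4 they lay inside Aida, 2183 bp from Brox (chromosome 1, 183299447 to 183299497, score 28.7), and near Tcp10c, Cpne4, Zfp825 (35464 bp, score 11.6) and Gm52481 on chromosome Y (1568 bp, score 10.2). For molar pSmad1/5 they lay inside Emp2 (score 11.7) and 1600014C10Rik (score 9.49), and for molar Smad4 inside Cwc22 (score 9.85). Strongest, here and below, means highest in score, which the deposited p-value of the BCP peak call did not always follow. For the shared limb pSmad1/5 peaks that p-value was 0.00041 at Smo and 0.000185 at Tcte2. At the lower-scoring Cbx7, Osr2 and Mest peaks it was 1.6e-09, 3.7e-07 and 5.4e-09. Whether the sites named here lie in problem regions was not tested, so their rank alone does not mark them as Smad targets.

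The second comparison asks how far occupancy is common to the tissues. For pSmad1/5, 395 molar peaks (1.11%, 1.01 to 1.23%) overlapped a limb peak, and 398 limb peaks (1.70%, 1.54 to 1.88%) overlapped a molar peak. For Smad4, 153 molar peaks (0.443%, 0.375 to 0.518%) and 154 limb peaks (0.518%, 0.439 to 0.606%) did. Fgf8, an epithelial growth factor gene of tooth and limb, had a pSmad1/5 site of both tissues 167 bp from its end (chromosome 19, 45742774), and Shh had one at 1368 bp (chromosome 5, 28458208); both were chosen after their values were seen.

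The pSmad1/5 sites of both tissues exceeded the local chance level by 4.70 times (4.25 to 5.19) and the Smad4 sites by 1.81 times (1.54 to 2.12). With a score of at least 4 on autosomes, 7 molar Smad4 peaks overlapped limb Smad4, 1.11 times local chance (0.447 to 2.29), and 446 of the 1000 local shifts gave as many. Near gene ends lay 45.8% of the molar pSmad1/5 peaks shared with limb (40.8 to 50.9%) and 14.0% of those not shared (13.7 to 14.4%). For molar Smad4 the shares were 17.6% (11.96 to 24.6%) and 4.77% (4.55 to 5.00%). Genes of dental epithelium had 5 of 32 members at pSmad1/5 sites of both tissues (percentile 99.2), and the Fgf family 4 of 22 (percentile 99.1).

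Across antibodies, molar pSmad1/5 coincided with limb Smad4 at 681 peaks (1.92%, 1.78 to 2.07%), a share above that with molar Smad4 (0.589%, 0.512 to 0.674%) beyond counting error. This was 5.63 times local chance (5.22 to 6.07). These sites lay within 50 kb of 8 of 45 limb patterning genes (percentile 99.8, which counts Hoxa9, Hoxa10 and Hoxa11 separately although they share a single site), among them Grem1, a secreted BMP antagonist, with a site 81 bp from a gene end (chromosome 2, 113758567). They also lay near 6 of 30 BMP-Smad target genes (percentile 99.5). In the HoxA cluster a single molar pSmad1/5 site, 636 bp from an end of Hoxa5, lay within 50 kb of 10 of 11 genes, so those genes are not separate observations. Limb pSmad1/5 coincided with molar Smad4 at 97 peaks, 1.58 times local chance (1.28 to 1.93). Molar pSmad1/5 thus exceeded local chance more at limb Smad4 (5.63 times) than at limb pSmad1/5 (4.70 times, 4.25 to 5.19). With equal numbers of peaks per chromosome the order was the same, 7.25 against 5.98, but the counting intervals overlapped. From molar pSmad1/5, overlap was therefore not larger for the same antibody. The same held from limb Smad4, at 5.62 times local chance with molar pSmad1/5 and 1.82 times with molar Smad4. Limb pSmad1/5 went the other way, at 4.73 times (4.28 to 5.22) with molar pSmad1/5 and 1.58 times with molar Smad4. Whether a shared peak marks binding by both proteins was not tested.

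Among the strongest peaks without a counterpart of the same antibody in the other tissue, molar pSmad1/5 and Smad4 peaks lay at Emp2 and Cwc22, and limb pSmad1/5 peaks at Cdk8, Smo and Cwc22. For limb Smad4 they included a peak inside Eps8 (chromosome 6, 137528978 to 137529031, score 16.5) and a peak 18117 bp from Cpne4 (chromosome 9, 104548561 to 104548721, score 11.7). Peaks near Tcp10c on chromosome 17 stood in both limb lists, at 13305936 to 13305987 for pSmad1/5 (score 10.1) and 13306038 to 13306080 for Smad4 (score 20.2). Molar Smad4 had a peak inside Fzr1 (score 9.495). The Cwc22 locus held 1 limb and 13 molar pSmad1/5 peaks and 3 limb and 36 molar Smad4 peaks within 50 kb.

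The third comparison asks which developmental genes had peaks in each tissue. Nearly all dental mesenchyme genes had a peak within 50 kb in each library. There were 39 of 40 for molar pSmad1/5, 37 for molar Smad4, 35 for limb pSmad1/5 and 36 for limb Smad4, where random lists had medians of 29, 28, 25 and 26. The percentiles were at least 99.97 in all 4 libraries. The excess of molar over limb, 4 genes for pSmad1/5 and 1 for Smad4, was that of random lists (medians of 4 and 1). The direction of this excess was not stable: with a score of at least 4, molar pSmad1/5 peaks lay near 11 of the 40 (percentile 83.5) and limb pSmad1/5 peaks near 15 (percentile 97.8), and within 10 kb Smad4 peaks lay near 24 in molar and 31 in limb.

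Within 1 kb of an end, 15 of 40 dental mesenchyme genes had a limb pSmad1/5 peak (random median 6, percentile 99.99) and 17 a limb Smad4 peak (8, percentile 99.885). There were 11 with a molar pSmad1/5 peak (9, percentile 81.0) and 3 with a molar Smad4 peak (3, percentile 47.2). The difference between libraries was not tested at this distance. Pax9, a paired-box regulator of tooth mesenchyme, had 5 molar pSmad1/5 peaks and 0 limb pSmad1/5 peaks within 50 kb, and 3 molar and 2 limb Smad4 peaks. Wnt5a also had 5 molar pSmad1/5 peaks and no limb pSmad1/5 peak. Both genes lie on chromosomes where the molar pSmad1/5 list goes down to a score of 2 and the limb list to 3. Their strongest molar pSmad1/5 peaks scored 3.75 and 3.67, so neither gene has a peak in either pSmad1/5 list with a score of at least 4. Sostdc1, an antagonist of BMP and Wnt signals, had a limb but no molar Smad4 peak, and Dkk1 a limb but no molar pSmad1/5 peak.

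Among other tooth regulators, Msx1 had 6 limb and 5 molar pSmad1/5 peaks, with a molar peak 59 bp from a gene end. Its limb Smad4 list had 3 peaks, the nearest at 66 bp, and its molar Smad4 list 1. Bmp4 had 3 limb and 4 molar pSmad1/5 peaks and 6 Smad4 peaks in each tissue. Barx1 had 7 limb and 9 molar pSmad1/5 peaks, Lhx6 4 and 4, Lhx8 5 and 5, Osr2 4 and 2, Msx2 1 and 4, and Runx2 5 and 1. Bmp4, Barx1, Lhx8 and Msx2 lie where the molar pSmad1/5 list goes down to a score of 2 and the limb list to 3.

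Limb patterning genes had peaks in 43 of 45 cases for molar pSmad1/5, 38 for limb pSmad1/5 and 40 for limb Smad4, all at percentile 99.955 or above. For molar Smad4 there were 30 of 45, close to the random median of 31 (percentile 38.9). The Smad4 difference of -10 lay at percentile 0.07 among random lists, whose median was 2. Of the 13 genes with a limb but no molar Smad4 peak, 12 lie on chromosomes 2, 5, 8, 9, 11 and 19, where the molar Smad4 list is sparse. Among random lists drawn from the same chromosomes the difference lay at percentile 6.55, and without Hoxa and Hoxd genes it was -5 at percentile 36.0. With a score of at least 4 it was -12 at percentile 0.83 among such lists, outside the random range, and -5 at percentile 20.2 without Hoxa and Hoxd genes.

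Hoxd13, Hand2 and Grem1 belong to these 13 genes. Grem1 had a limb Smad4 peak 99 bp from a gene end and 2 molar pSmad1/5 peaks. Sox9, a regulator of cartilage formation outside this list, had a limb Smad4 peak of score 6.29 inside the gene, no molar Smad4 peak, and 3 limb and 1 molar pSmad1/5 peaks. Shh had 5 limb Smad4 peaks, the strongest of score 5.92 at 1543 bp from an end, and no molar Smad4 peak. The limb regulators Lhx2 and En1 had 8 and 3 limb Smad4 peaks and no molar Smad4 peak. Tbx5, which sets forelimb identity, had 5 limb and 0 molar pSmad1/5 peaks, and 4 limb and 2 molar Smad4 peaks. Pitx1, a hindlimb and jaw regulator, had 5 limb and 10 molar pSmad1/5 peaks. Hoxa13 had 3 limb and 14 molar pSmad1/5 peaks, and Gli3 1 and 2. Pitx1, Hoxa13 and Gli3 too lie where the molar pSmad1/5 list goes down to 2: with a score of at least 4, Pitx1 had 0 limb and 1 molar and Hoxa13 0 limb and 2 molar pSmad1/5 peaks.

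**Figure D4:**
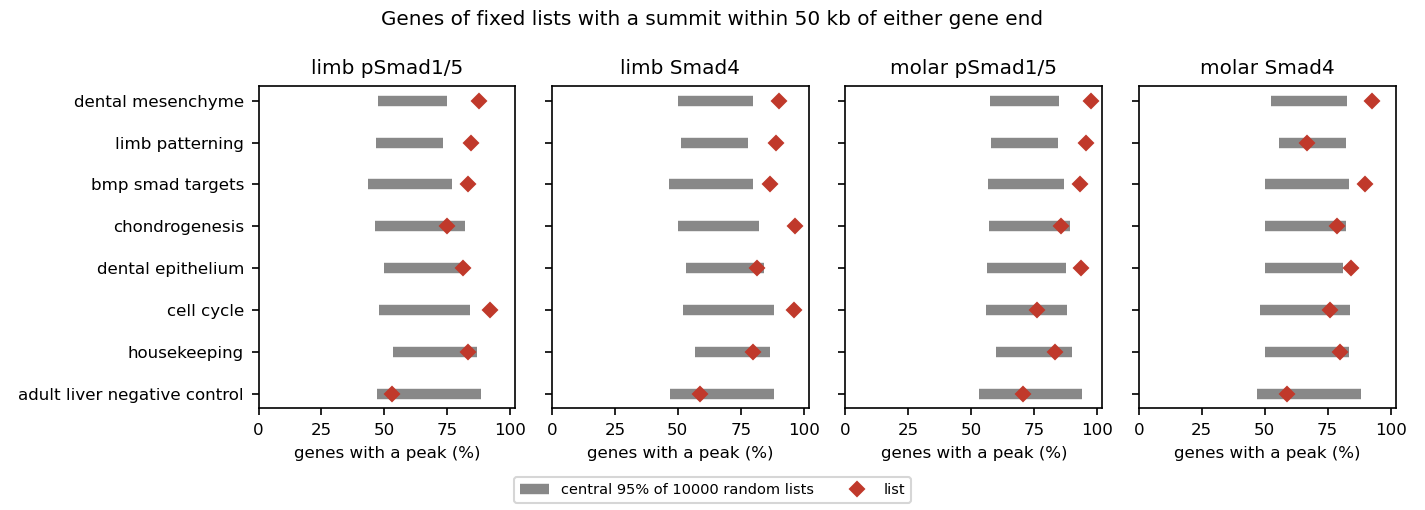
Percent of the genes of 8 fixed lists with a summit within 50 kb of either gene end (horizontal axis), per library. Diamonds are the lists and grey bars the central 95% of 10000 random lists; limb patterning genes reach 40 of 45 for limb Smad4 and 30 of 45 for molar Smad4.

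Direct targets of BMP-Smad signalling had peaks in 28 of 30 cases for molar pSmad1/5, 27 for molar Smad4, 25 for limb pSmad1/5 and 26 for limb Smad4, all at percentile 99.47 or above. Among random lists from the same chromosomes the limb counts fell within the central 95%, at percentiles 96.4 for pSmad1/5 and 96.7 for Smad4. The percentiles with a score of at least 4 were 99.87 for limb pSmad1/5, 87.8 for limb Smad4, 96.9 for molar pSmad1/5 and 96.8 for molar Smad4. The inhibitors of differentiation Id1 and Id2 had 5 and 3 limb and 6 and 4 molar pSmad1/5 peaks, and Id2, which lies where the molar pSmad1/5 list goes down to 2, had a limb pSmad1/5 peak 302 bp from a gene end. Id3 had 0 limb and 1 molar pSmad1/5 peak, and 9 limb Smad4 peaks with the nearest at 87 bp. The inhibitory Smads had 1 limb and 2 molar pSmad1/5 peaks at Smad6 and 7 and 3 at Smad7, where the nearest limb peak lay 358 bp from a gene end. Bambi, a BMP pseudoreceptor, had a molar pSmad1/5 peak 790 bp from an end and no limb pSmad1/5 peak. Bmper had a limb but no molar pSmad1/5 peak, and the Notch target Hey1 3 molar and 0 limb Smad4 peaks. Hey1 lies on chromosome 3, which holds 2393 molar and 1095 limb Smad4 peaks.

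Components of the BMP pathway had peaks in 22 of 31 cases for limb pSmad1/5 (percentile 78.5), 27 for limb Smad4 (99.3, but 96.35 with gene length also matched and 48.6 with a score of at least 4), 26 for molar pSmad1/5 (90.3) and 25 for molar Smad4 (92.2). Closer to the genes molar pSmad1/5 lay above random lists, with 21 within 10 kb (percentile 98.7, but 96.5 with gene length also matched) and 14 within 1 kb (99.79, or 99.37). Within 50 kb and with a score of at least 4 it reached 97.73 (93.7 with length matched). Limb pSmad1/5 was also above random lists within 1 kb, with 9 (97.6, but 95.8 with length matched). Within 10 kb the pSmad1/5 difference of molar minus limb was 5, inside the random range (percentile 73.1). The Smad4 gene and the co-receptor gene Rgmb each had 3 molar and 0 limb pSmad1/5 peaks. The receptor gene Acvr2b had 1 limb and 0 molar Smad4 peaks.

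Cartilage genes had limb Smad4 peaks in 27 of 28 cases (percentile 99.99) and molar Smad4 peaks in 22 (percentile 90.0), a difference of -5 within the central 95% of random lists (percentile 3.58). Within 10 kb the counts were 23 and 12, a difference of -11 outside that range (percentile 0.395). Within 50 kb the order turned with a score of at least 4, to 15 in limb and 16 in molar. That score was not tried within 10 kb. Besides Sox9, the receptor gene Pth1r (score 5.56) and the collagen gene Col9a3 (score 5.02) had limb but no molar Smad4 peaks, all on chromosomes where the molar Smad4 list starts at a score of 4. Nkx3-2 had limb but no molar pSmad1/5 peaks (score 4.95). Cartilage genes with pSmad1/5 peaks numbered 21 in limb and 24 in molar. Genes of the cell cycle had limb pSmad1/5 peaks in 23 of 25 cases (percentile 99.875) and molar pSmad1/5 peaks in 19 (percentile 56.0), and the difference of -4 lay at percentile 0.75 (0.84 among lists from the same chromosomes). Within 10 kb the counts were 15 and 13, a difference of -2 inside the random range (percentile 9.59). Within 50 kb and with a score of at least 4 they were 14 and 10. Mki67, a proliferation marker, had 2 limb and 0 molar pSmad1/5 peaks, and the replication genes Mcm2 and Mcm5 and the regulator E2f1 had 11, 3 and 4 limb Smad4 peaks and no molar Smad4 peak; Mcm5 and E2f1 lie where the molar Smad4 list starts at a score of 4. For Smad4 the cell cycle counts were 24 in limb and 19 in molar, a difference of -5 at percentile 4.50 (0.795 among lists from the same chromosomes). Dental epithelium genes had molar pSmad1/5 peaks in 30 of 32 cases (percentile 99.8) and limb pSmad1/5 peaks in 26 (percentile 97.2). This order, too, turned with a score of at least 4, to 9 in molar (percentile 64.25) and 13 in limb (87.65). In that list Sox2 and Foxi3 had 5 and 3 molar Smad4 peaks and no limb Smad4 peak, and Wnt10b had 8 limb and 0 molar Smad4 peaks. Sox2 and Foxi3 lie on chromosomes 3 and 6, which hold 2393 and 2133 molar against 1095 and 1588 limb Smad4 peaks. For each antibody, 18 lists and 21 families were examined, so a few extreme percentiles arise by chance.

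Markers of other cell types gave a measure of background in the 50 kb window, in which 67.3 to 74.4% of all protein-coding genes had a peak. Endothelial genes had molar pSmad1/5 peaks in 19 of 20 cases (percentile 98.8, or 97.15 with gene length also matched) and muscle genes limb pSmad1/5 peaks in 18 of 20 (percentile 99.2). Both lay within the random range with a score of at least 4, at percentiles 26.9 and 81.6. Nos3 and the muscle genes Acta1 and Lbx1 had limb but no molar Smad4 peaks, Tek, Robo4 and Met molar but no limb Smad4 peaks, and Tal1 and Mef2c molar but no limb pSmad1/5 peaks. Blood genes stood at 10, 10, 12 and 9 of 15 in the order limb pSmad1/5, limb Smad4, molar pSmad1/5 and molar Smad4, within the random range in each library. Of these, Spi1 and Cd68 had limb but no molar Smad4 peaks and Itgam the reverse. Nerve and neural crest genes stood at 11, 13, 12 and 11 of 15 in the same order. Tubb3 had limb but no molar Smad4 peaks, Isl1 and Elavl4 the reverse, and Foxd3 molar but no limb pSmad1/5 peaks. Epidermal genes stood at 12, 13, 12 and 13 of 15, with Col17a1 and Itga6 bearing limb but no molar pSmad1/5 peaks and Trp63 the reverse. Adult liver genes, a negative control, stood at 9, 10, 12 and 10 of 17, also within the random range, and housekeeping genes at 25, 24, 25 and 24 of 30. Within 10 kb, liver genes had limb Smad4 peaks in 2 cases (percentile 0.11) and molar Smad4 peaks in 8 (79.9), a difference of 6 at percentile 99.88. Nerve and neural crest genes had limb pSmad1/5 peaks in 5 and molar pSmad1/5 peaks in 12 at this distance, a difference of 7 at percentile 99.5. Ribosomal protein genes had pSmad1/5 peaks in 75 of 83 cases in molar (percentile 99.99) and 68 in limb (99.6), at 99.31 and 99.33 with a score of at least 4. Within 10 kb the ribosomal counts stood at 79.4 in molar and 97.55 in limb, or 99.995 and 100 with gene length also matched. Keratin genes had limb pSmad1/5 peaks in 44 of 49 (99.925). That count stood at 90.2 with gene length also matched, 92.6 among lists from the same chromosomes and 62.2 within 10 kb. An excess of this size within 50 kb thus also occurred outside the developmental lists, at ribosomal protein genes. Single-tissue members occurred in these controls too, as Tat (limb Smad4), Cyp2e1 and Cyp7a1 (molar Smad4), Uox (molar pSmad1/5), Polr2a (limb Smad4), Psmb2 (molar pSmad1/5) and Vps29 (molar Smad4). Of the single-tissue members above, Nos3, Acta1, Lbx1, Spi1, Cd68, Tubb3, Tat and Polr2a lie where the molar Smad4 list starts at a score of 4, and Mef2c, Trp63 and Uox where the molar pSmad1/5 list goes down to 2. Met, Tek, Itgam, Isl1, Elavl4, Cyp2e1 and Cyp7a1 lie on chromosomes with more molar than limb Smad4 peaks, and Robo4 and Vps29 on chromosomes with fewer. Olfactory receptor genes had few peaks, from 136 of 1106 for limb pSmad1/5 to 252 for molar Smad4, where random lists had medians of 788 and 721.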

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

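The data hold 1 library per group, so no sample was compared with others of its group. Peaks on the mitochondrial genome stood in the limb lists and not in the molar lists. The deposited lists were compared with these peaks included. There were 2 in the limb pSmad1/5 list, with summits at 14626 and 15058 and scores of 19.6 and 13.7, and 2 in the limb Smad4 list, at 2859 and 12419 with scores of 22.1 and 17.5. Their level in the input samples was not analysed here.

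The molar minus limb count of limb patterning genes was 5 for pSmad1/5, equal to the median of random lists (percentile 50.9). For Smad4 it was -10, at percentile 0.07 among random lists but 6.55 among lists from the same chromosomes. With a score of at least 4 the Smad4 difference was -12 at percentile 0.83 among lists from the same chromosomes, and -5 at percentile 20.2 without Hoxa and Hoxd genes. Since the pSmad1/5 count equals the random median, the opposite signs are no evidence of opposite trends. The difference between antibodies was not tested.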

How the results depend on the processing

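Local shifts, gene lists at shared sites, and tests at a minimum score of 4, with equal numbers of peaks per chromosome and with random lists matched on gene length or chromosome were chosen after the data were seen. The order of limb above molar in the sharing of pSmad1/5 with Smad4 held under all 9 alternatives, although the shares themselves moved with the definition of a shared site. Values follow in the order molar pSmad1/5 at molar Smad4, limb pSmad1/5 at limb Smad4, molar Smad4 at molar pSmad1/5, limb Smad4 at limb pSmad1/5, molar then limb pSmad1/5 at the other tissue, and molar then limb Smad4 at the other tissue.

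The higher-scoring 50% of each list gave 0.288%, 4.10%, 0.295%, 3.23%, 0.913%, 1.39%, 0.185% and 0.215%. Lists trimmed to the length of the shortest gave 0.351%, 4.06%, 0.351%, 4.07%, 1.36%, 1.38%, 0.359% and 0.359%. A score of at least 4 on autosomes gave 0.285%, 4.03%, 0.140%, 2.53%, 0.770%, 0.591%, 0.0978% and 0.0924%. Equal numbers per chromosome gave 0.292%, 3.71%, 0.292%, 3.73%, 1.23%, 1.25%, 0.266% and 0.266%. An overlap of at least 50% of both peaks gave 0.223%, 1.70%, 0.229%, 1.33%, 0.341%, 0.517%, 0.171% and 0.198%. Summits at most 200 bp apart gave 1.47%, 8.94%, 1.505%, 7.19%, 2.51%, 3.80%, 1.15% and 1.37%. Peaks within 1 kb of a gene end gave 0.686%, 12.8%, 2.10%, 8.35%, 3.55%, 5.25%, 1.62% and 0.542%. Peaks further away moved 4 shares, to 3.46% and 2.84% for limb pSmad1/5 and limb Smad4 within limb, and to 0.705% and 1.08% for molar and limb pSmad1/5 between tissues. Fewer or narrower matches lower a share by construction; the cause of the other shifts was not tested. Leaving out mitochondrial peaks and peaks of all 4 lists changed no share beyond its interval.

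Of the gene list counts, 55 stayed within 1.5 times of their value and 9 did not. With a score of at least 4, dental mesenchyme genes with a peak numbered 11 (molar pSmad1/5), 15 (limb pSmad1/5), 20 (molar Smad4) and 21 (limb Smad4), and limb patterning genes 23 (molar pSmad1/5), 17 (limb pSmad1/5) and 17 (molar Smad4). A window of 10 kb gave 24 dental mesenchyme and 19 limb patterning genes for molar Smad4. The dental mesenchyme difference of molar minus limb turned to -4 for pSmad1/5 with a score of at least 4. For Smad4 it turned to -1 with that score, to -2 with equal numbers per chromosome and to -7 within 10 kb; the cause was not tested. The limb patterning Smad4 difference stayed below 0 throughout, from -12 to -1. Other matching of random lists moved 14 list percentiles across the limits of the central 95% and left 382 on their side. Peak counts at the 22 named genes moved by over 1.5 times in 148 cases and not in 292. No paired analysis was possible because each group has 1 library. The motif alternative was not run, and unknown depth limits every comparison of list lengths.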

Other observations

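Of the tests below, only that of the deposited Smad4 lists against random lists from the same chromosomes had its prediction set down before its result was seen; the others were chosen after. Forkhead genes had peaks in 41 of 44 cases for limb pSmad1/5 and for molar pSmad1/5, 40 for limb Smad4 and 37 for molar Smad4, all at percentile 99.2 or above. The limb percentiles stayed at 99.7 or above with a score of at least 4, and the molar ones were 96.9 for molar pSmad1/5 and 85.2 for molar Smad4. Sox genes had molar pSmad1/5 peaks in 19 of 19 cases (percentile 99.9) and limb pSmad1/5 peaks in 15 (percentile 93.9); with a score of at least 4 the molar percentile was 96.975. Targets of TGF-beta and activin had molar peaks in 22 of 23 cases for pSmad1/5 (percentile 99.7) and 21 for Smad4 (percentile 99.45), and limb peaks in 19 cases each (97.2 and 93.7). The molar Smad4 count was inside the random range within 10 kb (8 genes, percentile 39.55, against 15 in limb) and with a score of at least 4 (percentile 79.6). Tgfbr1, a receptor of that branch, had 6 molar Smad4 peaks, the strongest of score 6.08, and no limb Smad4 peak, as had Tgif1 with 3. Acta2 had molar but no limb pSmad1/5 peaks. Wnt pathway genes had limb pSmad1/5 and limb Smad4 peaks in 34 of 40 cases each, molar pSmad1/5 peaks in 36 and molar Smad4 peaks in 29. Within 10 kb the Smad4 difference of molar minus limb lay below the random range for Wnt pathway genes (-12, percentile 1.185) and forkhead genes (-15, percentile 0.195). Within 50 kb both differences lay inside it, at -5 (percentile 6.63) and -3 (percentile 18.975). Among lists from the same chromosomes the 50 kb percentiles were 28.9 and 36.1, and no such lists were drawn for 10 kb. Wnt3a and Znrf3 had 16 and 4 limb Smad4 peaks and no molar Smad4 peak, Rspo3 had 3 molar and 0 limb Smad4 peaks, and Sfrp1 had 4 limb and 0 molar pSmad1/5 peaks. Fgf pathway genes had limb pSmad1/5 peaks in 18 of 20 cases (percentile 99.6) and molar pSmad1/5 peaks in 19 (percentile 99.1, but 89.9 with a score of at least 4). Fgf20 had 2 limb and 0 molar pSmad1/5 peaks, Spred2 4 limb and 0 molar Smad4 peaks, and Etv5 and Etv1 molar but no limb Smad4 peaks. Wnt3a, Znrf3 and Spred2 lie on chromosome 11, where the molar Smad4 list starts at a score of 4. Tgfbr1, Rspo3, Etv5 and Etv1 lie on chromosomes with more molar than limb Smad4 peaks, and Tgif1 on a chromosome with fewer. Bone genes had peaks in 11, 13, 14 and 14 of 16 cases in the order limb pSmad1/5, limb Smad4, molar pSmad1/5 and molar Smad4. Of these, Mef2c, Alpl and Spp1 had molar but no limb pSmad1/5 peaks and Ifitm5 the reverse.

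The HoxD cluster on chromosome 2 and its 50 kb flanks held 7 limb pSmad1/5, 6 limb Smad4 and 12 molar pSmad1/5 peaks, and 1 molar Smad4 peak. The HoxB cluster on chromosome 11 held 7, 13 and 12 peaks, and 1 molar Smad4 peak. On both chromosomes the molar Smad4 list starts at a score of 4 and the limb list at 3. With a score of at least 4, HoxD held 2 limb and 1 molar Smad4 peaks and HoxB 1 and 1. The HoxC cluster on chromosome 15, where both Smad4 lists start at 3, held 12 limb and 5 molar Smad4 peaks, or 4 and 2 with a score of at least 4. The HoxA cluster on chromosome 6 held 22 molar and 6 limb pSmad1/5 peaks, but the molar list starts there at 2 and the limb list at 3; with a score of at least 4 it held 3 and 0.

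Molar pSmad1/5 peaks coincided with Smad4 far less than limb pSmad1/5 peaks did. Unequal minimum scores alone are argued against, since with a score of at least 4 the molar overlap was 3.88 times local chance and the limb overlap 22.6 times, with intervals apart. Weak enrichment in the molar Smad4 library is a candidate explanation, because its overlap with limb Smad4 was 1.81 times local chance against 4.70 for pSmad1/5 between tissues, although binding of Smad4 at sites that differ between tissues would lower this overlap too. Gene lists go both ways on this: molar Smad4 peaks lay near 37 of 40 dental mesenchyme genes (percentile 99.97) and 27 of 30 BMP-Smad targets (99.6) within 50 kb, but these lists stood at percentiles 47.2 and 67.3 within 1 kb, and limb patterning genes at 38.9 within 50 kb. A true absence of Smad4 from molar pSmad1/5 sites stays open: molar Smad4 peaks near gene ends were 1.33 times local chance, and no second molar Smad4 library was used here.

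Fewer limb patterning genes had a molar than a limb Smad4 peak, and the tests exclude none of the explanations below. Sparse molar Smad4 peaks on 6 chromosomes may account for it: the test set down beforehand came out for this, at percentile 6.55 among random lists from the same chromosomes. Equal numbers of peaks per chromosome take that sparseness away. The difference was then -7, at percentile 0.63 matched on gene density, which goes against sparse peaks, but inside the random range from the same chromosomes (percentile 5.345). Without Hoxa and Hoxd genes it was -4 in that set, inside the random range in both (percentiles 3.125 and 18.1). With a score of at least 4, where those 6 chromosomes held 2809 molar and 2921 limb Smad4 peaks, the difference was -12 at percentile 0.83, which goes against sparse peaks and against the higher minimum score there, but without Hoxa and Hoxd genes it was -5, inside the random range (percentiles 20.2 from the same chromosomes and 4.515 matched on gene density). Repeated counting within Hox clusters stays open too, since without these genes the difference in the deposited lists was -5, at percentile 1.39 matched on gene density and 36.0 from the same chromosomes. Weak enrichment in the molar Smad4 library, the candidate above, was not tested for this pattern and stays open. The pattern was not particular to limb patterning genes. Within 10 kb the Smad4 difference also lay below the random range for cartilage (percentile 0.395), forkhead (0.195) and Wnt pathway genes (1.185). For other lists it lay inside that range, as for dental mesenchyme genes (percentile 8.14). A tissue difference in Smad4 binding at limb patterning genes was not tested apart from these explanations and stays open.

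At Cwc22, a splicing factor gene on chromosome 2 (77881159 to 77946356), the molar lists held 13 pSmad1/5 and 36 Smad4 peaks within 50 kb and the limb lists 1 and 3. More copies of the locus in the animals than in the reference genome could give such a cluster. All tissue is labelled as CD1 and the limb pSmad1/5 list has 1 peak there, but animals of an outbred stock can differ in copies, so this cannot be told apart from binding without the input libraries, which were not used here. No biological explanation was tested.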
